A study of Rattus norvegicus with 4 samples.

How the data were processed

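Sperm chromatin of Holtzman rats was digested with micrococcal nuclease and the protected DNA was sequenced. The labels describe 4 libraries of caudal epididymal spermatozoa: 2 controls, 1 from rats given cyproterone acetate and 1 from rats given tamoxifen. Per the labels' protocols, the spermatozoa were digested with 4 units of the nuclease at 37 °C for 2 minutes, a band of about 150 bp was cut from a gel, and libraries were made from 10 ng of DNA with 5 rounds of PCR. Each group held 6 animals, and the labels do not say how many animals went into a library.

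Per the submitters' processing notes, Bowtie2 and SAMtools 1.4 were used and the build was rn6. The program that called nucleosome positions is not given in the sources used here. The 6 tables analysed cover chromosomes 2 and X, each with 1 table for cyproterone acetate against both controls pooled, 1 for tamoxifen against the same pool and 1 for the 2 controls against each other. Each row is a nucleosome position. Occupancy at the summit is a coverage signal scaled by the authors, per the file headers. The log2 ratios of occupancy and of fuzziness, and the distance between the summits of the 2 sides in bp, are the authors' own, per the file headers. The false discovery rate (FDR), an adjusted p-value, was also computed by the authors, per the file headers. The fuzziness score, the spread of reads about a position, was deposited with each table. Another 16 columns with values of single libraries or of the pool were not used here.

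In the treatment tables the column headers name one side control and the other treated, and the values showed which library each side holds. The side headed control rose in steps of 1 fixed size, as a single library does, and the side headed treated held steps of 2 sizes. The ratio of those 2 sizes was 1.11 on chromosome 2 and 1.08 on X, the same as between the 2 control libraries. On chromosome 2 the pooled columns of both treatment tables had a correlation of 0.999 with each other across 279161 shared positions, and that of the cyproterone acetate table had one of 0.986 with the sum of both controls across 296844. The side headed control was therefore read as the treated library, and all deposited log2 ratios were turned so that a positive value means a higher value in the treated library. In the control table the headers do not tell replicate 1 from replicate 2, so the libraries are called the shallower and the deeper control, and ratios are shallower over deeper.

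The size of a step gave the value of 1 read. The steps were read as 8 times the mean depth of the libraries in the table divided by the depth of the library, per chromosome. In the pooled column of the treatment tables each of the 2 steps was read as that value divided by 2, as in a mean of both controls. Under this reading the harmonic mean of the steps is 8, as it was in all 6 tables. The depths themselves were inferred from the steps. On chromosome 2 cyproterone acetate was so placed at 1.52 times the depth of the shallower control, against 1.46 from reads at called positions. Dividing by the step turned summit coverage into read numbers in steps of 0.5 reads. Reads per window were counted for each library from 1 table: the treatment table for a treated library and the control table for the controls. A read of the pool is worth less than a read of the treated library (4.05 to 4.84 units on chromosome 2, against 6.37 for cyproterone acetate and 7.13 for tamoxifen). The median window ratio within the tables lay toward the treated side, by 0.11 (cyproterone acetate) and 0.12 (tamoxifen) on the log2 scale on chromosome 2, and by 0.32 and 0.35 on X, and the reason for this offset was not tested. Window ratios are therefore given relative to the median window of their chromosome.

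For each position table the percent of positions at least 2-fold apart, the percent with the authors' FDR at most 0.05, the median absolute log2 fuzziness ratio and the median summit distance were computed. Positions were then averaged in windows of 100 kb with at least 20 positions, and the spread of the log2 ratio was taken over windows. The spread that counting alone gives was computed from the read numbers. Intervals of spreads and correlations are 95% bootstrap intervals over windows, and those of rank correlations and of the correlations between treatments with no control in common are over blocks of 1 Mb, each with 1000 draws. Intervals of means at strong positions are bootstrap intervals over single positions, also with 1000 draws. Intervals of read ratios cover counting error only, since PCR copies carry no molecular identifiers. A pseudocount of 0.5 reads was added to window counts. To see how both treatments correlate when neither changed anything, 1000 sets of libraries were drawn from the control shares with Poisson counts and the extra variance of the control pair. That variance was the same for all windows of a chromosome. In a test on simulated data with 200 of 4166 windows changed by 1.5-fold, 99.5% (cyproterone acetate) and 98.5% (tamoxifen) of the changed windows lay beyond the 97.5th percentile of the simulated control pair, as did 0.983% and 1.11% of the unchanged ones. With a change of 1.3-fold, 80.0% and 82.5% were recovered. Those draws held Poisson noise alone.

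With 1 library per treatment no test across libraries was made, and the control pair is the only replicate spread. Nothing in the labels says that the 2 controls came from separate animals, so their spread may be technical. The rule for named items, fixed before the data were examined, was to name promoters and, with no annotation of the files' build at hand, the 5 highest and 5 lowest 100 kb windows of each treatment. The gene table at hand is of another assembly than rn6, so promoters, named genes and the 11 gene lists fixed in advance were not analysed here. The alternatives changed the fold and FDR thresholds, the occupancy filter, the pseudocount, the centring, the window size, the mean and the control library used. Others were chosen after seeing the data: positions by read number, reads counted per library, at most 3 reads counted per position, and every setting of the correlation between treatments. The correlation between treatments, the 1 kb bins, the strong positions, the position density and the ratio of X to chromosome 2 were also chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.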

Results

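Nucleosomes that remain in sperm were mapped in adult rats treated by mouth for 60 days with 1 of 2 drugs that act on steroid hormone signalling. Cyproterone acetate, an antagonist of the androgen receptor with progestogen activity, was given at 20 mg per kg per day. Tamoxifen, a selective modulator of the estrogen receptors, was given at 0.4 mg per kg per day, and the controls received water. The series asked how nucleosome occupancy of sperm differs with and without these treatments. Most histones of mammalian sperm are replaced by protamines, so the nuclease-resistant fragments of about 150 bp come from the part of the genome that keeps nucleosomes. There was 1 library for each treatment and 2 for the controls, and positions on chromosome 2 and on the X chromosome (build rn6) were analysed.

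Coverage was low in every library. At the called positions of chromosome 2 the cyproterone acetate library held 1563294 reads, the tamoxifen library 1311684, and the controls 1067555 (shallower) and 1170574 (deeper). On X the corresponding numbers were 471468, 361722, 312317 and 337218. Of the positions with reads on chromosome 2, 45.2% had 1 read or less with cyproterone acetate, 48.4% with tamoxifen, and 50.3% and 50.5% in the controls. On X these shares were 60.0%, 63.9%, 62.2% and 64.8%.

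The first comparison was between the 2 control libraries, the only replicate spread at hand. Each treatment was set against both controls pooled, so the control pair is not on the same scale as the treatments. In the authors' deposited table for chromosome 2, 78.3% of 868880 positions differed at least 2-fold between the controls, 31.1% higher and 47.3% lower in the shallower library. For X, 86.5% of 341280 positions in the authors' deposited table differed at least 2-fold. In the authors' deposited tables the occupancy FDR was at most 0.05 at 15.7% of the positions of chromosome 2 and 24.5% of those of X. Only 42.0% of the positions on chromosome 2 and 26.0% of those on X had reads in both controls.

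Over all positions, occupancy differed at least 2-fold less often between cyproterone acetate and the pooled controls than between the 2 controls, and this order turned at better covered positions. Reads lay on both sides at 55.3% of positions on chromosome 2 and 36.8% on X, against 42.0% and 26.0% for the control pair. Positions without reads on one side were thus rarer against the pool, so the order over all positions does not measure an effect. In the authors' deposited table for chromosome 2, 75.5% of 969963 positions were at least 2-fold different, 37.4% higher and 38.1% lower with cyproterone acetate. Set against 1 control at a time, rescaled to equal medians at 296844 matched positions, the split became 24.4% higher and 45.8% lower over the deeper control, and 27.6% and 41.9% over the shallower one. On X, 82.9% of 380301 positions in the authors' deposited table differed at least 2-fold, 49.2% higher and 33.7% lower, and against the deeper control alone 30.9% were higher and 45.1% lower. Matched positions had to be called in the control table too, which favours positions with control reads, and the rescaling shifts all positions alike, so the change of the split cannot be assigned to the control left out. The occupancy FDR in the authors' deposited tables was at most 0.05 at 13.4% of positions on chromosome 2 and 23.6% on X, against 15.7% and 24.5% for the control pair. At or above the median occupancy, 69.0% of positions on chromosome 2 and 79.1% on X were at least 2-fold different with cyproterone acetate, against 61.8% and 73.4% for the control pair. With 10 or more reads on at least 1 side it was 85.8% and 72.3%, against 59.6% and 35.3%.

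Tamoxifen likewise gave lower shares at least 2-fold different than the control pair over all positions. Here too the scale was unlike, with reads on both sides at 55.3% of positions on chromosome 2 and 36.9% on X, against 42.0% and 26.0%. In the authors' deposited table for chromosome 2, 72.2% of 895443 positions were at least 2-fold different, 33.1% higher and 39.1% lower. For X, the authors' deposited table gave 81.0% of 330961 positions, 42.9% higher and 38.1% lower. Against the deeper control alone the split was 20.9% higher and 50.0% lower on chromosome 2, and 25.7% and 49.5% on X. The occupancy FDR in the authors' deposited tables was at most 0.05 at 16.6% of positions on chromosome 2 and 24.9% on X, slightly above the 15.7% and 24.5% of the control pair. At or above the median occupancy it was below the control pair, at 20.4% against 27.9% and 45.0% against 48.4%. At or above the median occupancy, 62.8% of positions on chromosome 2 were at least 2-fold different with tamoxifen, above the 61.8% of the control pair, and 70.7% on X, below its 73.4%. With 10 or more reads on at least 1 side it was 82.5% and 66.0%. That filter sums both controls on the pooled side, so the positions it takes differ in kind from those of the control pair.

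These calls rested on few reads. Among positions on chromosome 2 with an FDR of at most 0.05 in the authors' deposited tables, 86.4% (cyproterone acetate), 88.5% (tamoxifen) and 93.7% (control pair) had no read on one side. On X the shares were 94.6%, 88.1% and 96.5%. A position with 3 reads against 0 had a median FDR of 0.0234 in the authors' deposited table of the control pair on chromosome 2, while an exact two-sided binomial test of 3 reads against 0 at equal depth gives p = 0.25. These calls therefore did not tell a treatment from the spread between control libraries.

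**Figure D1:**
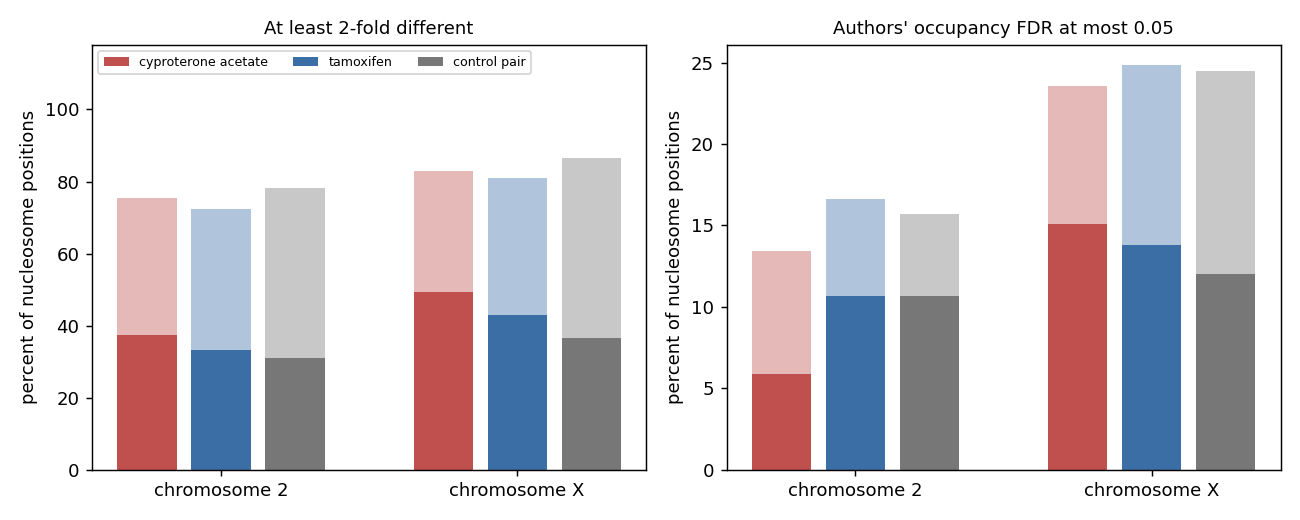
Percent of nucleosome positions at least 2-fold different (left) and with the authors' occupancy FDR at most 0.05 (right) on chromosomes 2 and X. Dark parts are positions higher in the treated library (control pair: in the shallower control) and light parts are positions lower in it; the bars of both treatments and of the control pair lie close together, at 75.5%, 72.2% and 78.3% for a 2-fold difference on chromosome 2.

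Fuzziness was lower in the treated libraries than in the pooled controls, but how far this exceeded the control pair depended on the positions taken. The median log2 fuzziness ratio in the authors' deposited table was -0.13 for cyproterone acetate and -0.12 for tamoxifen on chromosome 2, and -0.25 and -0.23 on X, against 0.01 on both chromosomes for the control pair. At or above the median occupancy the control pair was at -0.08 on chromosome 2, as far from 0 as cyproterone acetate (-0.07) and close to tamoxifen (-0.09). On X it was at -0.02 there, against -0.19 and -0.17. Fuzziness depends on the read number, so positions with equal read numbers of 3 or more on both sides were compared. There the median ratio was -0.09 for cyproterone acetate (19674 positions) and -0.13 for tamoxifen (17892 positions) on chromosome 2, and -0.03 for the control pair (8793 positions). On X it was -0.09, -0.15 and -0.01. The pool joins reads of 2 libraries, which alone can widen a position, and no single control library was set against the treated ones for this score. Where both sides had reads, the median summit distance in the authors' deposited tables was 20 bp for each treatment and 30 bp for the control pair on chromosome 2, and 10 bp (cyproterone acetate), 15 bp (tamoxifen) and 30 bp (control pair) on X.

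Over 100 kb windows the treated libraries spread more than the control pair within the authors' tables, but not in every count of reads. The SD of the log2 occupancy ratio within the tables was 0.164 (95% interval 0.158 to 0.170) for cyproterone acetate and 0.165 (0.160 to 0.170) for tamoxifen, against 0.147 (0.142 to 0.151) for the control pair. Counting reads per library, the SD beyond that expected from counting was 0.117 for cyproterone acetate, 0.122 for tamoxifen and 0.0714 for the control pair over 4166 windows. On X the SD of these read ratios, counting error included, was 0.165 and 0.175 against 0.176 for the control pair, which has the largest counting error. With at most 3 reads counted per position the SD over both chromosomes was 0.123 for cyproterone acetate, below the 0.134 of the control pair, and 0.136 for tamoxifen. Part of the spread thus came from stacks of many reads at single positions. Beyond counting it was 0.0678 (cyproterone acetate), 0.0798 (tamoxifen) and 0.0277 (control pair). The counting error may be overstated under this limit. On chromosome 2 the control pair had an SD of 0.110, below the 0.115 computed from counting. On X alone the values beyond counting were 0.0842, 0.0932 and 0.0618, in the same order. All window values below are relative to the median window of the chromosome.

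With cyproterone acetate the 5 highest windows lay on chromosome 2 and near the start of X. The window of chromosome 2 from 1300001 to 1400000 was at 1.16 on the log2 scale, with 1546.5 reads against 439 and 536 in the controls. With at most 3 reads counted per position it kept 0.36, the highest of the 5. The windows of chromosome 2 from 49300001 to 49400000, 197100001 to 197200000 and 193500001 to 193600000 were at 1.09, 1.08 and 0.96, and that of X from 300001 to 400000 at 0.99. Their values with at most 3 reads per position were 0.17, 0.01, 0.08 and 0.04. In the window at 193500001 the 5 strongest positions held 44.6% of the cyproterone acetate reads.

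The lowest windows with cyproterone acetate were mainly on X. The window of X from 18200001 to 18300000 was at -1.10, with 723.5 reads against 969 in the shallower and 889.5 in the deeper control, and at -0.59 with at most 3 reads per position. From read counts its log2 value was -0.89, with a counting interval of -1.02 to -0.77. The control pair differed there by 0.24, and tamoxifen was at -0.53. The nearby window of X from 17900001 to 18000000 was at -0.72 (tamoxifen -0.50), that from 140900001 to 141000000 at -0.79 (tamoxifen -0.34) and that from 123800001 to 123900000 at -0.70 (tamoxifen -0.39). From read counts the window at 140900001 was at -0.61 over both controls, -0.77 over the shallower control and -0.43 over the deeper one. The window at 17900001 was at -0.41, -0.52 and -0.30 in the same order. The lowest window of chromosome 2, from 133600001 to 133700000, was at -0.61 on 32 reads. Its counting interval around the value from read counts, -1.25 to 0.03, included 0.

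With tamoxifen the highest window was the one of chromosome 2 from 193500001 to 193600000, at 1.09, with 1257.5 reads against 480 and 496.5 in the controls. It fell to 0.04 with at most 3 reads per position. The window of chromosome 2 from 24500001 to 24600000 was at 0.71 and kept 0.37 under that limit, with 858.5 reads against 442.5 and 462 and a value of 0.54 with cyproterone acetate. Thinly covered windows of X made up the rest. That from 99600001 to 99700000 was at 0.81 on 96 reads. That from 59700001 to 59800000 was at 0.76, but from read counts it was 0.20 over the shallower control and 0.91 over the deeper one. That from 500001 to 600000 was at 0.75 with only 21 positions, and the control table held fewer than 20 positions there.

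The lowest windows with tamoxifen also had few reads. The window of X from 144900001 to 145000000 was at -1.14 on 14 reads against 27 and 31.5, with a counting interval of -2.11 to -0.30 around the value from read counts. That of X from 149700001 to 149800000 was at -0.86 (108 reads) and that of X from 88800001 to 88900000 at -0.64 (52 reads). From read counts the window at 88800001 was at -0.57 over both controls, -0.80 over the shallower control and -0.31 over the deeper one. On chromosome 2 the windows from 163800001 to 163900000 and from 162900001 to 163000000 were at -0.76 and -0.53.

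Both treatments were then set against each other, since they share the same controls. Across windows, which are not independent replicates, the log2 changes had a Pearson correlation of 0.646 within the authors' tables. From reads counted per library it was 0.588, against 0.372 (95% range 0.339 to 0.404) in simulated unchanged libraries set against the same controls. The covariance was 0.0146 against a simulated 0.00530. With each treatment set against a different control library the correlation was 0.279 or 0.342, depending on the assignment. At a limit of 0.35 on the log2 scale, set from the control pair, 64 windows were higher with cyproterone acetate and 97 with tamoxifen, and 37 were higher with both. Simulated unchanged libraries gave 14.96 and 19.38 higher windows on average, with 2.81 (at most 10) in both, and independent lists would share 1.49. The simulation gave all windows of a chromosome the same extra variance. It may therefore hold too few extreme windows, such as those with read stacks, and overstate the excess. Lower windows numbered 32 and 50, with 7 in both, against 17.7 and 24.2 on average, with 2.46 (at most 8) in both, in the simulation and 0.384 for independent lists. The control pair, 1 library against 1 and so not on the scale of the treatments, had 46 windows above this limit and 59 below it. The limit was a percentile of the absolute control-pair values, so the total of these windows was fixed by that choice. Only the split into higher and lower windows was free to vary, and the total cannot be compared with the numbers of the treatments. With at most 3 reads per position the windows higher with both fell to 15, against 3.65 on average and at most 10 in the simulation. With 1 library left on each side the controls could not be split further, so part of the excess over independent lists may come from the shared controls.

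**Figure D2:**
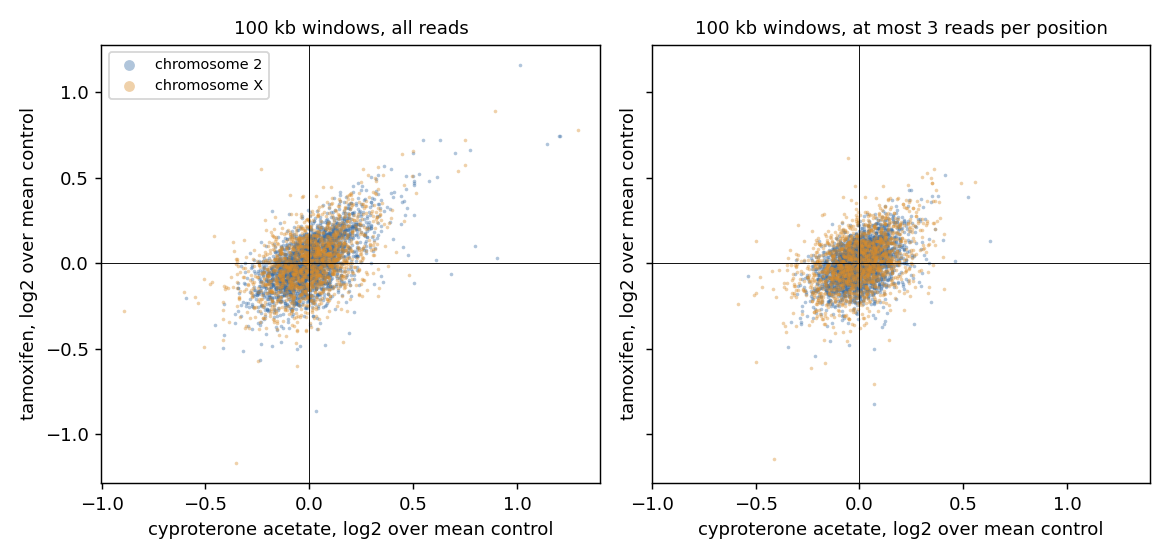
Log2 change of 100 kb windows with cyproterone acetate (horizontal) and tamoxifen (vertical), each over the mean of both controls, relative to the median window of the chromosome; each point is 1 window of chromosome 2 or X. Counting all reads (left) the correlation was 0.588, and counting at most 3 reads per position (right) it was 0.443, with the points at the upper right drawn in; simulated unchanged libraries gave 0.372 and 0.380 (95% range 0.345 to 0.417).

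The fullest 1 kb bins, chosen on the mean share over all 4 libraries, held a larger share of the treated reads at most of the sites so chosen. Treated reads take part in that choice, which favours bins full in those libraries. On chromosome 2 the 1 kb bin from 193572001 to 193573000 held 629 reads with cyproterone acetate, 617 with tamoxifen, and 118.5 and 95.5 in the controls. That is a share 4.21 times (counting interval 3.60 to 4.91) and 4.92 times (4.21 to 5.75) that of the controls, while the 2 controls differed by 1.36 times. The bins of chromosome 2 from 49364001 to 49365000 and from 156860001 to 156861000 were 3.03 and 3.48 times the controls with cyproterone acetate, and 2.21 and 2.28 times with tamoxifen. On X the 5 fullest bins all lay between 36446001 and 36470000. Those starting at 36446001, 36450001 and 36467001 were 3.52, 3.37 and 3.67 times the controls with cyproterone acetate and 2.62, 2.57 and 2.89 times with tamoxifen. Those starting at 36453001 and 36469001, in the same stretch, were 1.12 and 0.835 times, with cyproterone acetate, and their counting intervals included 1. Chosen on the controls alone, bins at 10 or more times the mean of chromosome 2 (24 bins) held 0.274% of the cyproterone acetate reads and 0.218% of the tamoxifen reads, against 0.124% and 0.140% in the controls. On X (83 bins) the shares were 1.15% and 1.13% against 1.04% and 1.01%. Of the 5 fullest bins by the controls alone, a choice that favours bins full in the controls, those of chromosome 2 starting at 193572001, 49364001 and 156860001 remained, and that starting at 160885001 was at 1.70 times the controls with cyproterone acetate and 0.703 times with tamoxifen. On X none of the 3 raised bins remained, and the 5 bins so chosen lay between 0.554 and 1.25 times the controls with cyproterone acetate (3 below 1) and between 0.551 and 1.195 times with tamoxifen (4 below 1).

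**Figure D3:**
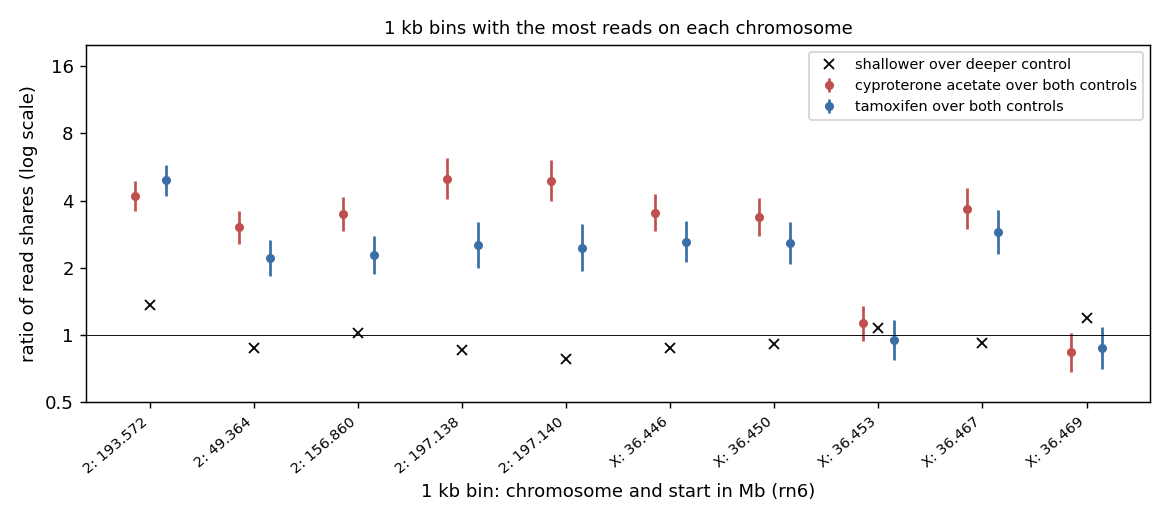
Share of reads in the 5 fullest 1 kb bins of chromosome 2 and of X by the mean over all 4 libraries, as the ratio of each treated library to both controls (circles, with 95% counting intervals) and of the shallower to the deeper control (crosses), on a log axis. The bins of X starting at 36453001 and 36469001 lie near 1 and all others above the controls in both treated libraries.

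Tamoxifen changes on chromosome 2 rose with the number of called positions in a window. With windows in 5 equal groups by that number, the median change was -0.04 in the group with the fewest positions (median 225 per window) and 0.09 in the group with the most (median 421). The rank correlation across 2607 windows was 0.321 (95% interval 0.272 to 0.366), against 0.106 for cyproterone acetate and -0.0705 for the control pair. With at most 3 reads per position it was 0.280 for tamoxifen and -0.0246 (-0.0737 to 0.0276) for cyproterone acetate. On X it was 0.098 for tamoxifen. The change is small, below the SD of single windows.

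**Figure D4:**
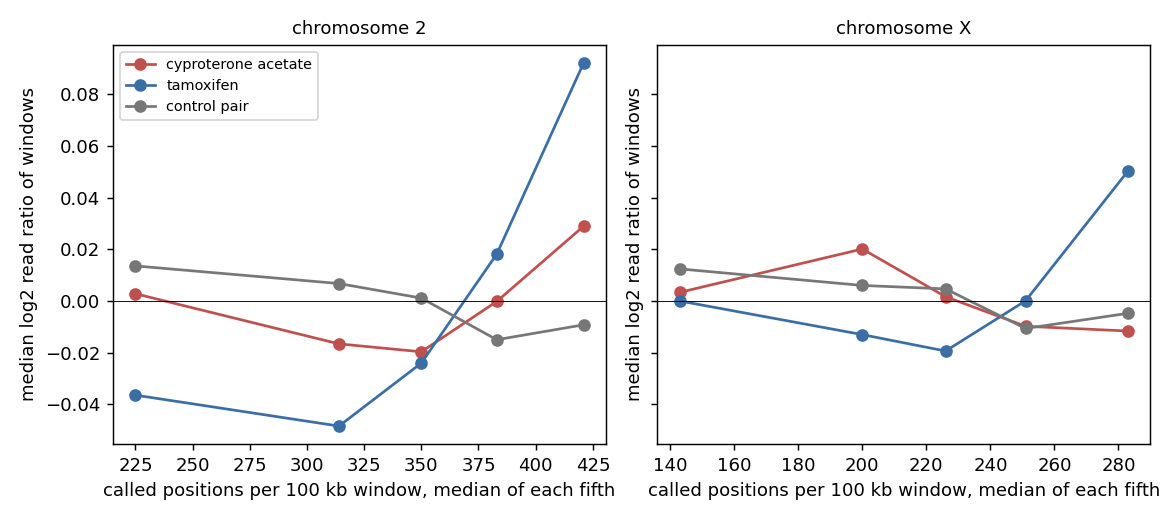
Median log2 change of 100 kb windows in 5 equal groups of windows by the number of called positions in the control table, for chromosome 2 (left) and X (right); the control pair is the shallower over the deeper control. The tamoxifen line on chromosome 2 runs from -0.04 in the sparsest group to 0.09 in the densest.

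The balance between X and chromosome 2 also differed between libraries. For 100 reads on chromosome 2 the tamoxifen library had 27.6 reads on X (95% counting interval 27.5 to 27.7), the cyproterone acetate library 30.2 (30.1 to 30.3), and the controls 29.3 (29.1 to 29.4) and 28.8 (28.7 to 28.9). These sums run over called positions, of which 240298 on X and 700884 on chromosome 2 held reads with tamoxifen. Depths were also inferred from the step sizes of the authors' scaling, without a sum over called positions. From these the ratio was 93.0% of the shallower control with tamoxifen, 102% with cyproterone acetate and 97.7% in the deeper control. The tamoxifen value lay below both controls and that of cyproterone acetate above both. The range of the 2 controls is the only replicate spread, and a further control library could also fall outside it. By the scaling, cyproterone acetate lay nearer to the shallower control than the deeper control did, and by read counts it lay farther. The counting intervals do not measure the spread between libraries.

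**Figure D5:**
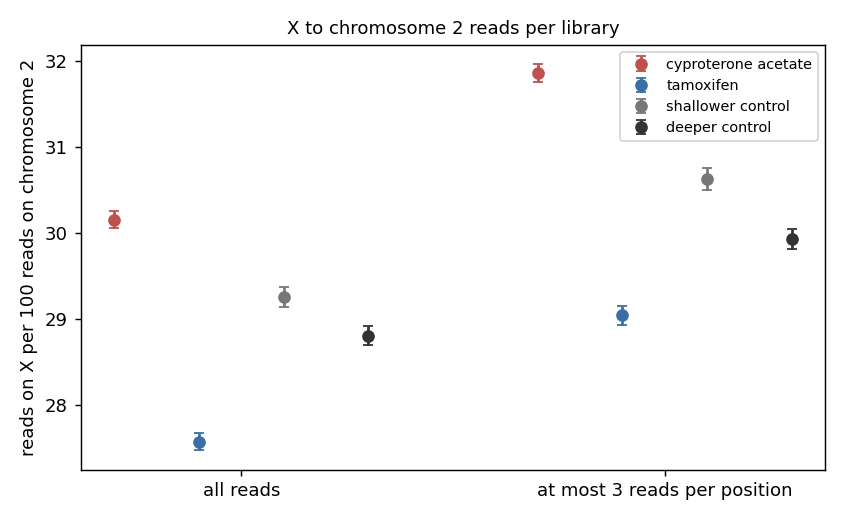
Reads on X per 100 reads on chromosome 2 in each library, counting all reads (left) or at most 3 reads per position (right), with 95% counting intervals; the vertical axis does not start at 0. Tamoxifen (27.6) lies below both controls (29.3 and 28.8) and cyproterone acetate (30.2) above them.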

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

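Of 180 alternative values, 107 stayed within the limits set for the main value (1.5 times for a percent of positions, the 95% interval otherwise), and 73 moved. Most of these values cannot change sign. The signed fuzziness ratio of the control pair, 0.01 on both chromosomes, fell below 0 in 3 settings on each, to -0.08 and -0.02 at or above the median occupancy. Leaving aside centring and rescaling, which shift all positions alike, the larger of the higher and lower parts turned in 11 of 42 alternatives for 2-fold positions, and in 6 of 18 for the FDR. On chromosome 2 the 2-fold split (higher/lower) went from 37.4%/38.1% to 38.5%/26.7% with a pseudocount and 40.6%/28.2% at the point of largest difference for cyproterone acetate, and from 33.1%/39.1% to 35.4%/28.4% and 37.0%/28.9% for tamoxifen. On X both treatments turned with 3 or 10 or more reads on a side, and tamoxifen at or above the median occupancy. The control pair turned on both with 10 or more reads (chromosome 2: 31.1%/47.3% to 42.3%/17.3%). At an FDR of at most 0.01 the split on chromosome 2 went from 5.86%/7.58% to 1.92%/1.43% for cyproterone acetate and from 10.7%/5.96% to 1.58%/1.72% for tamoxifen; both turned there at or above the median occupancy too, and the control pair at 0.01 on both chromosomes. The percent of positions at least 2-fold different stayed within 1.5 times in 55 of 56 alternatives (not for the control pair on X, at 35.3% with 10 or more reads on at least 1 side), and leaving out a control library gave 68.1% to 76.0% over both treatments and chromosomes. Its order against the control pair turned in 10 of 32 alternatives, from below to above it: for both treatments on both chromosomes with 10 or more reads (85.8% and 82.5% against 59.6% on chromosome 2, 72.3% and 66.0% against 35.3% on X), for cyproterone acetate on both at or above the median occupancy (69.0% against 61.8%, 79.1% against 73.4%) and with 3 or more reads (76.8% against 75.4%, 86.1% against 83.8%), and for tamoxifen on chromosome 2 at or above the median occupancy (62.8% against 61.8%) and on X at 1.5-fold (92.0% against 91.4%). The order turned in 5 of 12 alternatives for the FDR and 7 of 16 for fuzziness (values below). Alternatives by read number, reads per library or at most 3 reads per position, and all of the correlation between treatments, were chosen after seeing the data. Where no reason is given, the cause was not tested. Values below are for cyproterone acetate, tamoxifen and the control pair, in this order.

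At an FDR of at most 0.01 in the authors' deposited tables, 3.35%, 3.30% and 3.13% of positions passed on chromosome 2 and 6.96%, 5.71% and 6.00% on X. At or above the median occupancy, where single reads are left out by construction, it was 21.5%, 20.4% and 27.9% on chromosome 2, and 46.1%, 45.0% and 48.4% on X. The median absolute log2 fuzziness ratio, 0.376, 0.394 and 0.493 on chromosome 2 and 0.50, 0.527 and 0.720 on X, moved to 0.306, 0.313 and 0.355, and to 0.412, 0.416 and 0.448, at or above the median occupancy. With reads on both sides it was 0.254, 0.266 and 0.243, and 0.253, 0.286 and 0.193, so the larger main value of the control pair rested on positions without reads on one side. At equal read numbers of 3 or more it was 0.223, 0.231 and 0.230, and 0.233, 0.247 and 0.226. The median summit distance was 0 bp over all positions, since nearly all positions without reads on one side are listed at 0. It was 15, 20 and 20 bp on chromosome 2 at or above the median occupancy. With reads on both sides it was 20, 20 and 30 bp, and 10, 15 and 30 bp on X.

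The SD of the log2 ratio was 0.0715, 0.0782 and 0.0518 over 1 Mb windows, and 0.308, 0.276 and 0.0759 with the median in place of the mean, which takes few distinct values at this depth. It was 0.153 for cyproterone acetate from reads per library, and 0.123, 0.136 and 0.134 with at most 3 reads per position, where cyproterone acetate passed below the control pair (0.119 to 0.126 against 0.130 to 0.139) and tamoxifen no longer exceeded its interval. Leaving out a control gave 0.159 to 0.180 for cyproterone acetate and 0.171 to 0.184 for tamoxifen. The correlation between treatments (0.646) was 0.599 by rank, 0.588 from reads per library, 0.605 over 1 Mb windows and 0.443 with at most 3 reads per position, where simulated unchanged libraries gave 0.380 (0.345 to 0.417). Leaving out a control gave 0.625 to 0.691, and with no control in common it was 0.279 or 0.342.

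Promoter results, gene lists and the correlation of promoter changes, with their alternatives, were not run, since no annotation of the build was at hand. No paired analysis was possible with 1 library per treatment, and no result comes from a test. The depth limits single positions: a median of 1 to 2 reads where any were present leaves 2-fold differences within counting error.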

Other observations

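All tests in this part were chosen after the results were seen, except those of X to chromosome 2 by reads per position and by median window, which were set before their values were seen. With 1 library per treatment, a difference between libraries made on different occasions cannot be separated from a treatment, and the labels name no batch.

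On chromosome 2, positions with many reads in one treated library were fuller in the other than in the controls. There, 105 positions had 20 or more reads with cyproterone acetate among 156287 positions matched in all tables. Per unit of depth they averaged 23.1 reads with cyproterone acetate (95% bootstrap interval 20.5 to 26.4) and 22.5 with tamoxifen, against 6.93 and 7.0 in the controls. The cutoff of 20 reads used the cyproterone acetate library alone. A matched position, however, also had to be called near the same place with tamoxifen and in the controls, which can favour positions where the libraries are alike. The 137 positions chosen in the same way with tamoxifen averaged 24.2 (22.6 to 25.9) and, with cyproterone acetate, less at 18.2 (15.9 to 20.7), against 5.71 and 4.94 in the controls. Among the 150 positions with 10 or more reads in the shallower control (mean 13.2), the deeper control averaged 7.28 (6.08 to 8.66), cyproterone acetate 7.88 (5.44 to 10.5) and tamoxifen 7.70 (5.88 to 9.59). The deeper control had 92 such positions. They averaged 11.4 in the shallower control, 14.2 (10.6 to 18.1) with cyproterone acetate and 12.8 (10.0 to 16.2) with tamoxifen. At 20 or more reads, 15 positions of the shallower control averaged 24.2 in the deeper one, 29.0 with cyproterone acetate and 23.7 with tamoxifen. The 14 of the deeper control averaged 24.6 in the shallower one, 42.3 with cyproterone acetate and 31.1 with tamoxifen. On X the 40 positions with 10 or more reads in the shallower control averaged 18.1 there, 14.8 (10.8 to 19.0) in the deeper one, 26.0 (12.6 to 41.4) with cyproterone acetate and 20.5 (11.8 to 32.2) with tamoxifen. The 9 positions of X with 20 or more reads in the shallower control averaged 33.2 (24.9 to 41.5) in the deeper one, 77.6 (36.3 to 124) with cyproterone acetate and 58.1 (26.7 to 94.5) with tamoxifen. The intervals of these means draw single positions. Neighbouring positions of a read stack are not independent, so the intervals may be too narrow.

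The first pattern weighed was the window changes shared by both treated libraries. Noise of a single control library cannot be the whole cause. With no control in common the lower of the 2 correlations was 0.279 (95% block interval 0.229 to 0.325). Whatever both controls share stays in either assignment, so this split cannot exclude it. Read stacks at few positions explain part of the shared changes. With at most 3 reads per position the covariance fell from 0.0146 to 0.00736 (simulated 0.00464). The lower correlation with no control in common was then still 0.113 (0.0706 to 0.157). Read counts per library kept 83.8% of the covariance within the tables. Treated reads were still counted at positions called in the treatment tables, and control reads at those of the control table. That count therefore does not remove position calling, which stays open. A common response to both treatments may remain, as may a difference in library preparation or in GC bias between treated and control libraries, neither of which was tested.

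The second was the rise of tamoxifen changes with position density on chromosome 2. Counting at most 3 reads per position left 0.280 (0.234 to 0.323) of a rank correlation of 0.321, which argues against read stacks. Depth is argued against by cyproterone acetate, the deepest library, at 0.106 (0.0538 to 0.160), and at -0.0246 (-0.0737 to 0.0276) with at most 3 reads per position. Bias by GC content or mappability could follow density and stays open, since no genome of the build was at hand, as does an effect of tamoxifen.

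The third was the lower ratio of X to chromosome 2 reads with tamoxifen. With at most 3 reads per position it was 29.0 per 100 (28.9 to 29.2), below the lower control at 29.9 (29.8 to 30.0), which argues against read stacks. The median window of X was at 45.1 per 100 of the median window of chromosome 2 (44.2 to 46.1), below the lower control at 47.1 (46.3 to 47.9), which argues against a few windows of either chromosome. A lower share of X-bearing sperm or a lower retention of nucleosomes on X with tamoxifen may account for it, as may composition bias of the library, and none of these was tested.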
